A study of Mus musculus with 16 samples.

How the data were processed

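RNA was sequenced in bulk from dissected mouse hearts of 4 groups, with 4 hearts in each group and 16 libraries in all. The groups were wild-type (WT) and systemic Armh4 knockout (KO) mice, each at 8 weeks (young) and at 25 months (aged), per the labels. The hearts within a group were described as independent biological replicates. Each heart is named here by its group and its animal number. The titles of the 4 young WT samples begin with other letters than their genotype label, and the genotype label and the table's column names were used. No animal number occurs in more than 1 group, so hearts could not be paired. Aged KO animals were numbered 114 to 125 and aged WT animals 1 to 12, and no sequencing batch, cage or date was given in the sources used here.

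The deposited count table holds expected counts per gene, which need not be whole, and the deposited FPKM table holds values that the authors scaled by library size and gene length. HISAT, Bowtie2 and the mouse genome build GRCm39 are named in the submitters' processing notes, without versions or roles; the counting program is not given in the sources used here. Between 9.57% and 10.5% of the counts in a library were not whole numbers (tolerance 1e-09), and counts were rounded before testing. Such counts can arise where reads are shared between similar genes, and some near-identical genes are marked as uncertain. Gbp2, Gbp3, Gbp5 and Gbp7 had whole counts in all 16 libraries. H2-DMb1, H2-D1, H2-T23, Cd209f and Oas3 had fractional counts in 10, 6, 3, 12 and 7 libraries, so their values may be affected too. Both tables list 18346 genes by Entrez identifier and symbol, 226 of them with no count in any library. FPKM values followed the counts of the same library across genes, after centring, with correlations of 0.989 to 0.995, against at most 0.724 with any other library.

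Total counts ranged from 11456503 to 13298660 per library. The 10 most abundant genes took 11.9% to 14.2% of the counts. No pair of hearts in a group agreed within sampling noise: the lowest chi-square per degree of freedom was 3.67, so no library was treated as a repeat of another.

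Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, after filterByExpr and TMM scaling, which left 13373 genes. All 16 libraries entered 1 fit with 4 groups and 12 residual degrees of freedom. Adjusted p-values for single genes are from that test with the Benjamini-Hochberg method, and a gene is said to have risen, fallen or changed where its adjusted p was under 0.05. Fold changes are given as log2 values with their standard errors, and levels as CPM (counts scaled to library size), mean ± SD over 4 hearts. The 4 comparisons of groups were KO with WT at each age and aged with young in each genotype. The interaction is the ageing change in KO hearts minus that in WT hearts.

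Before the data were examined, 40 gene lists were fixed, made of pathways of heart ageing and markers of cell types that a dissected heart can hold. The 35 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, and again with the correlation estimated for each list. A p from the second run is named as a p with an estimated correlation. Where the members of a list that passed are counted, the count is given over all genes and also adjusted over the list alone. Only tested members are counted, which were 5 of 18 T and NK cell markers and 5 of 11 neutrophil markers. A weakly expressed marker could enter the test through a single group where it was high, which favours a difference for that group. A list score is the mean over members of log2 CPM (prior count 2) after centring each gene over the 16 libraries.

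The genes named in the text follow a rule that was also fixed before the data were examined. It names Armh4, Nnt (part of it is deleted in the C57BL/6J substrain), Xist and 4 Y-chromosome genes. In each comparison of groups it adds up to 8 genes with curated symbols and the largest rise and 8 with the largest fall, among those with an adjusted p under 0.05, no overlap between the hearts of the groups and at least 1 CPM in the higher group. It adds up to 4 members of each list in order of adjusted p, and for the interaction the 5 largest values in each direction. Names at the end of these orders and a few others were left out.

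Ratios of genes with few counts are given with exact 95% intervals, which cover counting error only. Single scores were compared by exact two-sided permutation tests. For comparisons that share libraries, unchanged groups were simulated 20 times, and the aged WT hearts were also divided into 2 and 2 in all 6 ways so that no library was shared.

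The fit was tested on simulated data in which 200 genes were changed and the sarcomere list was raised by 0.5 on the log2 scale. Calls of sarcomere genes were not counted as false. In the comparison of aged KO with aged WT hearts (13258 genes), edgeR recovered 67.2% of changes of 1.5-fold, 97.0% of 2-fold and 97.0% of 4-fold, with 4.95% false calls, and DESeq2 (13373 genes) gave 9.63% false calls. Recovery of 2-fold changes was 80.6% for KO with WT in young hearts (13269 genes), 86.6% for ageing in WT (13281 genes), 77.6% for ageing in KO (13254 genes) and 74.6% for the interaction (13258 genes). Each value rests on a single draw of 67 genes, with the same gene means and spread in every group. The values therefore do not rank the 4 comparisons of groups by power. The wider spread of aged WT hearts was not simulated.

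Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors within edgeR, limma voom with quality weights, other filters on low counts, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) with and without a filter at a mean FPKM of 0.5. Also fixed were a fit of only the 8 libraries compared, camera with an estimated correlation, Spearman correlations, and leaving out each library in turn. Scores of atrial and of blood genes as covariates were added after the data had been seen. Reference transcripts of another mouse build were used for transcript length, GC content and the order of genes around Armh4, so no coordinates are given.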

Results

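Gene expression was measured by bulk RNA sequencing in 16 mouse hearts, 4 each from young WT, aged WT, young KO and aged KO animals, to ask how loss of Armh4 affects the ageing heart. Total counts were 11456503 to 13298660 per heart. The main axis of variation over the 13373 genes tested held 40.7% of the variance and separated aged from young hearts. On it WT_Aged_1 lay farthest out. Y-chromosome genes were expressed in every heart at mean log2 CPM of 5.45 to 5.85. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those for lists are from camera.

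Armh4 (Entrez 67419), the targeted gene, separated the genotypes in every heart. It stood at 15.5 ± 2.49 CPM in young WT and 18.5 ± 1.94 CPM in aged WT hearts (SD, n = 4), with 158 to 254 counts per library. In KO hearts it stood at 0.374 ± 0.198 CPM when young and 1.14 ± 0.368 CPM when aged (SD, n = 4), with 1 to 22 counts. The log2 change in KO was -5.33 ± 0.25 (SE) in young hearts (edgeR adjusted p = 5.1e-11) and -4.01 ± 0.21 in aged hearts (adjusted p = 2.31e-10). Within WT hearts the ageing change of Armh4 was 0.26 ± 0.15 and did not pass (adjusted p = 0.24). Within KO hearts the few remaining counts rose with age by 1.59 ± 0.36 (adjusted p = 0.00941), a call that was lost on the log2(FPKM + 1) scale. None of the 20 tested genes nearest to Armh4 changed in KO hearts at either age by edgeR, and 2 of them had an unadjusted p under 0.05 at each age.

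**Figure D1:**
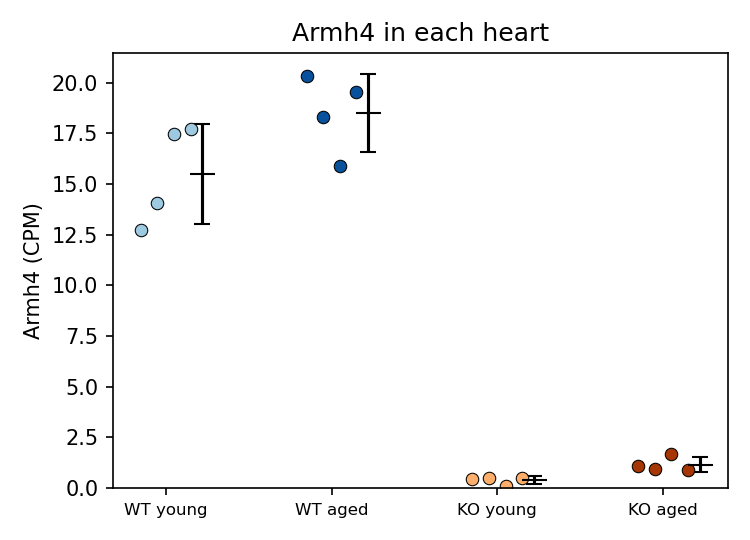
Armh4 in CPM (vertical axis) in each of the 16 hearts (points), by group, with the group mean and SD (bars, n = 4). The 8 KO hearts lie at or below 1.68 CPM and the 8 WT hearts at or above 12.7 CPM.

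Ageing of WT hearts was accompanied by higher expression of interferon-induced, antigen presentation and myeloid genes. Of 35 interferon-stimulated genes 34 rose, and all 35 adjusted over the list alone, with a median log2 change of 1.82 (camera adjusted p = 1.4e-39; adjusted p = 0.028 with an estimated correlation). Gbp5, a guanylate-binding protein, rose by 2.15 ± 0.17 (SE) from 9.45 ± 1.71 to 41.9 ± 8.7 CPM (SD, n = 4; edgeR adjusted p = 1.01e-07), and Gbp2 by 1.89 ± 0.16. Of 20 antigen presentation genes 19 rose, also 19 adjusted over the list alone, with a median of 1.76 (adjusted p = 0.0519 with an estimated correlation). Among them H2-DMb1, which loads class II molecules, rose by 1.74 ± 0.23 and the non-classical class I gene H2-T23 from 30.3 ± 1.6 to 85.8 ± 27.6 CPM. Of 18 macrophage markers 15 rose (17 adjusted over the list alone, median 1.36, adjusted p = 0.0111 with an estimated correlation), including the mannose receptor Mrc1 by 1.40 ± 0.12 and the lectin gene Cd209f by 3.62 ± 0.25.

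Other immune lists moved the same way. Complement genes rose in 14 of 18 cases (15 adjusted over the list alone; 1 fell), with C6 of the terminal pathway up by 4.32 ± 0.47 and C1qa of the classical pathway by 1.34 ± 0.15. Chemokine and acute inflammation genes rose in 21 of 28 cases (24 adjusted over the list alone). Neutrophil markers rose in 4 of 5 cases (5 adjusted over the list alone), with the calprotectin genes S100a9 and S100a8 up by 5.09 ± 0.49 and 5.83 ± 0.80. These lists each had adjusted p = 0.028 with an estimated correlation, as did the antioxidant and the lysosome and autophagy lists. Antioxidant genes rose in 16 of 29 cases and fell in 1 (18 and 3 adjusted over the list alone), with Gstm2 up by 0.82 ± 0.08 and G6pdx by 0.75 ± 0.11. Lysosome and autophagy genes rose in 13 of 38 cases and fell in 2 (also 13 and 2 adjusted over the list alone), with the cathepsins Ctsl up by 0.71 ± 0.09 and Ctss by 2.02 ± 0.23. Of the T and NK cell markers 3 of the 5 tested rose, also 3 adjusted over the list alone, with Cd8a up by 3.10 ± 0.53 and the receptor gene Il7r by 2.09 ± 0.38 (adjusted p = 0.287 with an estimated correlation). That list lost its call without WT_Aged_4 (adjusted p = 0.0688) or WT_Aged_1 (adjusted p = 0.0555). Erythroid markers rose in 8 of 9 cases, also 8 adjusted over the list alone, including Hbb-bs by 1.59 ± 0.29 (adjusted p = 0.105 with an estimated correlation). The adult beta globin genes are near-identical, so the split of their reads is uncertain. Senescence genes rose in 9 of 20 cases and fell in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). Cell cycle genes rose in 7 of 26 cases and fell in 1, also 7 and 1 adjusted over the list alone, with the proliferation marker Mki67 up by 1.13 ± 0.22 (adjusted p = 0.511 with an estimated correlation).

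The matrix and heat shock lists were called lower with age in WT hearts, at the preset correlation only. Of 35 matrix genes 14 fell and 1 rose (15 and 2 adjusted over the list alone), among them the basement membrane collagen Col4a1 by -1.20 ± 0.13 and Col6a2 by -1.01 ± 0.11 (adjusted p = 0.365 with an estimated correlation). Heat shock genes fell in 15 of 22 cases, also 15 adjusted over the list alone, with the co-chaperone Dnajb5 at -0.79 ± 0.12 (adjusted p = 0.0562 with an estimated correlation). Hspa1a at -2.33 ± 0.47 and Hspa1b at -2.37 ± 0.53 encode nearly the same Hsp70 protein, so their separate values are uncertain. Immediate early genes fell in 8 of 24 cases (12 adjusted over the list alone), with Klf4 at -0.79 ± 0.13 and Klf2 at -0.73 ± 0.14 (adjusted p = 0.259 with an estimated correlation). Ion channel and calcium genes fell in 7 of 25 cases and rose in 1, also 7 and 1 adjusted over the list alone, with the potassium channel Kcna5 at -1.06 ± 0.17 (adjusted p = 0.439 with an estimated correlation). Smooth muscle and pericyte markers fell in 4 of 14 cases (also 4 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation). Ribosomal protein genes rose in 3 of 77 cases (1 adjusted over the list alone; adjusted p = 0.786 with an estimated correlation), a call that was lost without WT_Aged_1 (adjusted p = 0.421).

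Among curated genes whose groups did not overlap, the largest rises in WT ageing were those of Apol9a (6.84 ± 1.37), the ubiquitin-like modifier gene Ubd, Chil3, the B cell chemokine Cxcl13 (6.29 ± 1.29), the protease inhibitor Serpina3f, S100a8, the monocyte chemokine Ccl8 (5.64 ± 0.42) and Plac8 (5.51 ± 0.97). Aged WT hearts were uneven in some of these, at 10.5 ± 13.9 CPM for Apol9a, 12.1 ± 17.3 for Cxcl13 and 4.89 ± 5.76 for Chil3 (SD, n = 4). Young WT hearts held only 1 count of Ubd, 2 of Chil3 and 3 of Serpina3f, so their ratios of counts were 148 (95% interval 26.2 to 5899), 116 (31.9 to 966) and 69.6 (23.5 to 340). On the same terms the largest falls were those of the decarboxylase Ddc (-3.09 ± 0.49), the skeletal calsequestrin Casq1 (-2.72 ± 0.46), Plekhh1 (-2.51 ± 0.27), skeletal actin Acta1 (-2.42 ± 0.43), Nrk (-2.38 ± 0.49), the Hsp70 genes and the calcium-binding protein gene Necab1 (-2.31 ± 0.34). In all, 2906 genes changed, 1578 up and 1328 down (54.3% up), and 762 changed more than 2-fold. On the log2(FPKM + 1) scale 71.5% of 2460 changed genes were up. At 2896 genes (21.7%) no aged heart overlapped a young one, against 2.86% by chance. With a blood score as covariate only 297 genes were called, and blood genes themselves rose with age, as given above.

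**Figure D2:**
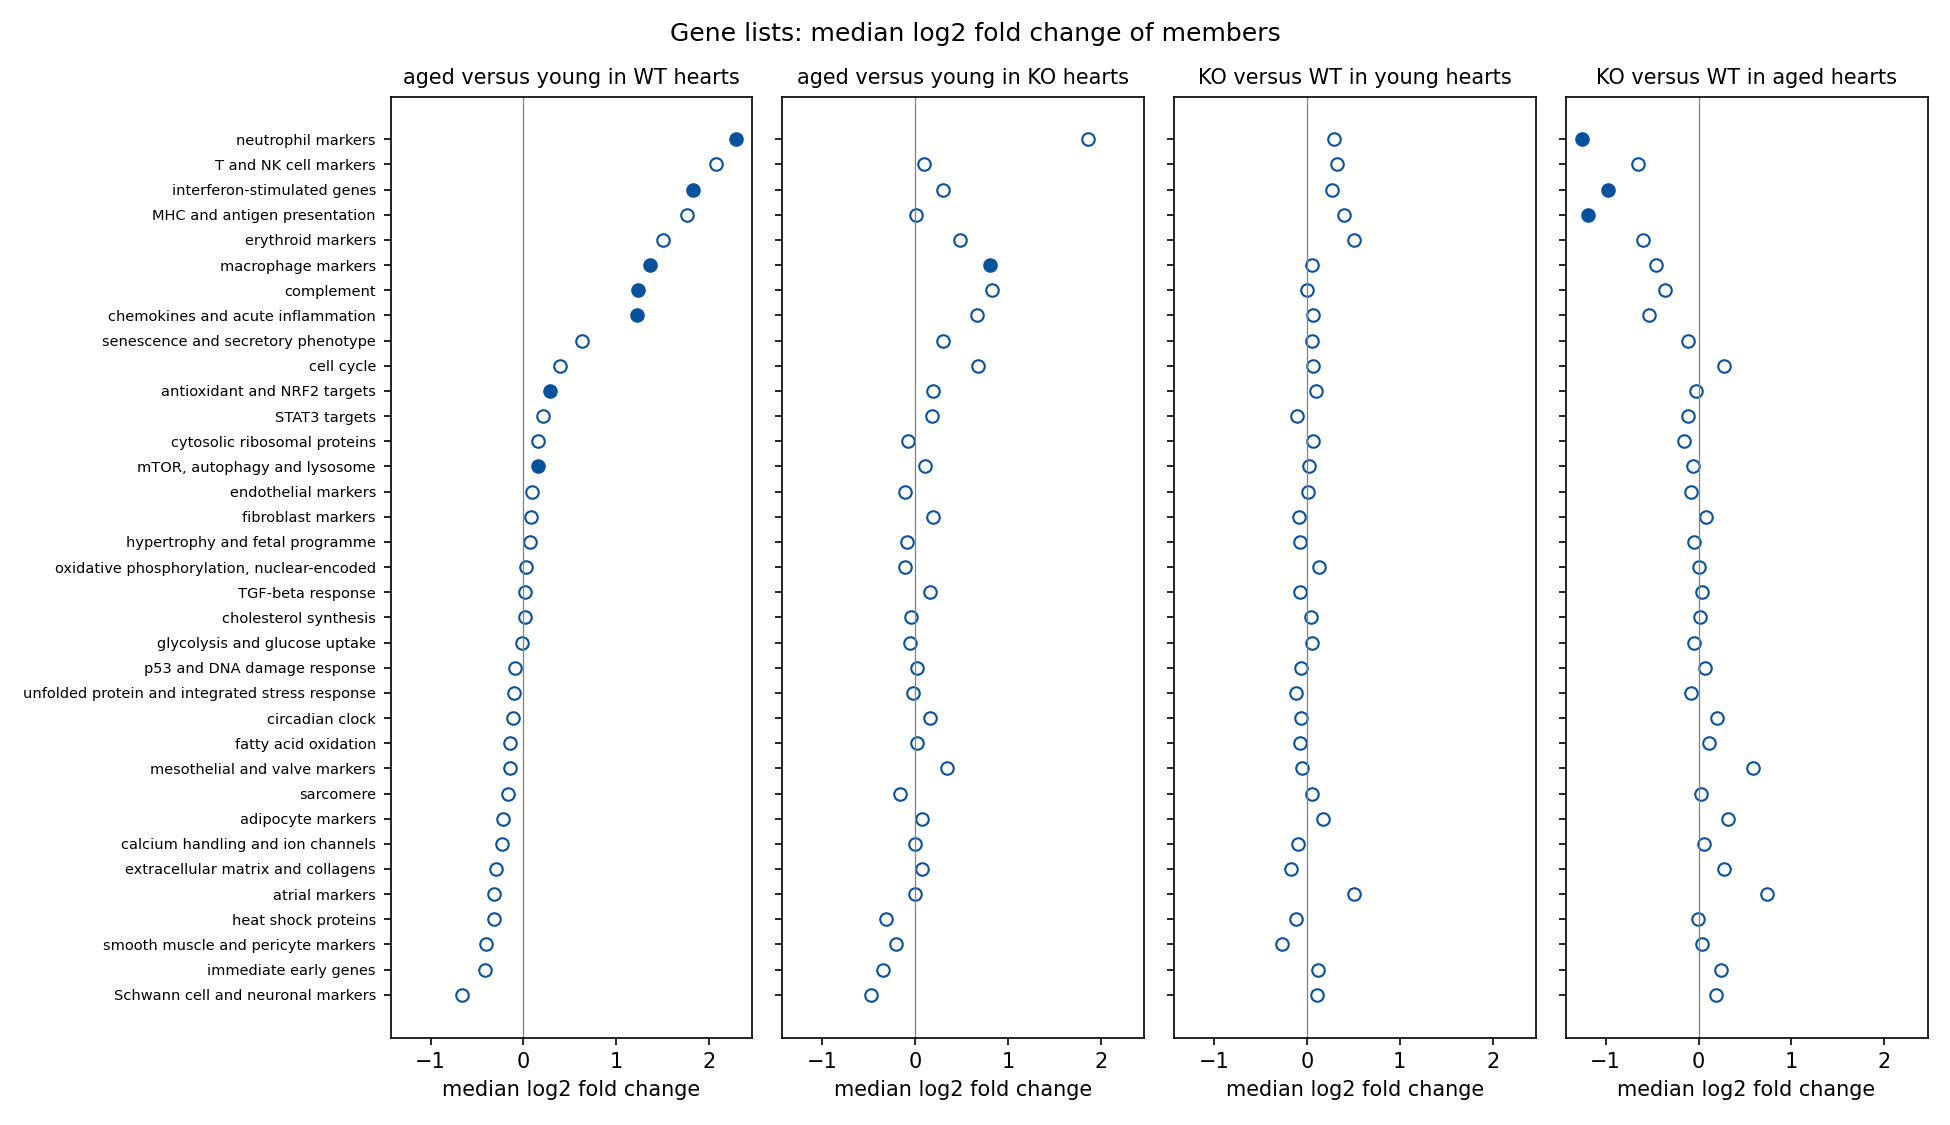
Median log2 fold change of the members of 35 gene lists (horizontal axis) in the 4 comparisons of groups, with lists ordered by their value in WT ageing. Filled points mark lists called with an estimated correlation, which were 7 in WT ageing, 1 in KO ageing, 0 in young KO against WT and 3 in aged KO against WT.

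In aged hearts, loss of Armh4 was accompanied by lower expression of interferon-induced and antigen presentation genes. Of 35 interferon-stimulated genes 12 fell in aged KO against aged WT hearts (31 adjusted over the list alone), with a median log2 change of -0.98 (camera adjusted p = 3.5e-61; adjusted p = 0.0163 with an estimated correlation). The guanylate-binding protein genes Gbp7 (Entrez 229900), Gbp2 (14469), Gbp5 (229898) and Gbp3 (55932) changed by -1.67 ± 0.17, -1.36 ± 0.15, -1.31 ± 0.16 and -1.71 ± 0.20 (SE), with edgeR adjusted p of 6.15e-05, 0.000175, 0.00024 and 0.000588. Gbp7 stood at 33.4 ± 5.43 CPM in aged KO and 106 ± 28.4 CPM in aged WT hearts (SD, n = 4), and these 4 calls held under every alternative run. Of 20 antigen presentation genes 12 fell (19 adjusted over the list alone), with a median of -1.18 (adjusted p = 0.0218 with an estimated correlation). The class I light chain B2m changed by -1.36 ± 0.22, H2-D1 by -1.10 ± 0.19, H2-T23 by -1.02 ± 0.18 and H2-DMb1 by -1.09 ± 0.21. WT_Aged_12 lay close to the aged KO hearts in both list scores. Its interferon score was 0.37, against 0.33 in KO_Aged_114, and its antigen presentation score 0.10, against 0.03 in KO_Aged_125.

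Some leucocyte genes were also lower in aged KO hearts. Neutrophil markers fell in 2 of 5 cases (4 adjusted over the list alone, median -1.25, adjusted p = 0.0242 with an estimated correlation), namely S100a9 by -2.15 ± 0.36 and the receptor gene Csf3r by -1.25 ± 0.25. Of 18 macrophage markers 1 fell, Mrc1 at -0.52 ± 0.11, and 12 fell adjusted over the list alone (median -0.45, adjusted p = 0.0514 with an estimated correlation). C1qa, at -0.58 ± 0.14, did not pass (adjusted p = 0.0682). The T cell co-receptor Cd8a fell by 2.43 ± 0.48 on the log2 scale, as 1 of 5 T and NK cell markers (2 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation). Of 28 chemokine and acute inflammation genes 2 fell (11 adjusted over the list alone), Ccl8 at -1.39 ± 0.28 and Il1b at -1.80 ± 0.34 (adjusted p = 0.123 with an estimated correlation). Of 18 complement genes 1 fell (8 adjusted over the list alone), C6 at -1.79 ± 0.34 (adjusted p = 0.224 with an estimated correlation). Senescence genes fell in 2 of 20 cases (also 2 adjusted over the list alone; adjusted p = 0.445 with an estimated correlation).

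Further lists were called only at the preset correlation. Matrix genes had a median of 0.28, with 1 of 35 up over all genes and 7 adjusted over the list alone (adjusted p = 0.373 with an estimated correlation). Col6a2 rose by 0.49 ± 0.11 and Col6a3, at 0.64 ± 0.16, did not pass (adjusted p = 0.0659). Atrial markers had a median of 0.74 with none of 10 passing over all genes and 4 adjusted over the list alone (adjusted p = 0.123 with an estimated correlation). The atrial genes Myl4 and Myl7 differed by 3.79 ± 1.22 and 6.55 ± 2.21 and did not pass, nor did Sln (adjusted p = 0.228, 0.259 and 0.319), while Kcnj3 differed by 0.34 ± 0.11 (adjusted p = 0.202). Sln stood at 17.3 CPM in KO_Aged_114 and at most 3.81 CPM in the other aged KO hearts, while aged WT hearts held 2 counts of it. Erythroid markers had a median of -0.60 with none of 9 passing, over all genes or the list alone (adjusted p = 0.245 with an estimated correlation), and Alas2 stood at -0.73 ± 0.27. The remaining called lists had medians of -0.16 for ribosomal proteins, -0.08 for the unfolded protein response, 0.06 for ion channels and calcium, 0.08 for fibroblast markers, 0.11 for fatty acid oxidation, 0.20 for the clock, 0.25 for immediate early genes, 0.27 for the cell cycle and 0.59 for mesothelial and valve markers, none of them called with an estimated correlation. With single hearts left out, 10 of the 20 list calls held and 10 were lost in some fit. Lost were 3 without KO_Aged_114 (adjusted p = 0.0509 to 0.622), 5 without KO_Aged_115 (0.0513 to 0.228), 4 without KO_Aged_122 (0.115 to 0.17), and 5 without KO_Aged_125 (0.0583 to 0.181). Likewise lost were 3 without WT_Aged_12 (0.0834 to 0.123), 4 without WT_Aged_4 (0.0525 to 0.0843), 3 without WT_Aged_5 (0.0918 to 0.638) and 5 without WT_Aged_1 (0.059 to 0.383). The interferon, antigen presentation, macrophage and neutrophil calls were not among those lost.

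Among curated genes whose groups did not overlap, the largest changes in aged KO hearts after Armh4 were falls. They were those of Irgm2 (-3.07 ± 0.63), Tgtp2 (-2.92 ± 0.43), Ubd (-2.61 ± 0.45), Tgtp1 (-2.49 ± 0.39), Cd8a and Cd274, which encodes the checkpoint ligand PD-L1 (-2.37 ± 0.46), followed by S100a9. Aged WT hearts were uneven in Irgm2 (388 ± 394 CPM; edgeR adjusted p of the fall = 0.0459) and in Cd274 (83.8 ± 68.3 CPM; SD, n = 4). Tgtp1 and Tgtp2 are near-identical interferon-inducible GTPase genes and every library held fractional counts of both, so their separate values are uncertain. The rises were those of Necab1 (2.13 ± 0.35), Smim3 (0.81 ± 0.18), the chloride channel Clcn1 (0.80 ± 0.17), the somatostatin receptor Sstr3 (0.69 ± 0.16), Fam171a2 (0.66 ± 0.16), the proteoglycan Podn (0.64 ± 0.10), the collagen chaperone Fkbp10 (0.63 ± 0.12) and Lrfn4 (0.62 ± 0.14). In all, 117 genes changed, 22 up and 95 down, and 53 changed more than 2-fold. At 674 genes (5.04%) the groups did not overlap, against 2.86% by chance. The count was 31 without KO_Aged_115, 34 without KO_Aged_122 and 251 without WT_Aged_12. Of the 30 named calls 11 held whichever heart was left out. These were Armh4, Necab1, Podn, Tgtp2, Ubd, S100a9, B2m, Gbp2, Gbp3, Gbp5 and Gbp7. Of the others, 19 ended without KO_Aged_115 (adjusted p = 0.0551 to 0.159), 18 without KO_Aged_122 (0.0515 to 0.219), 7 without KO_Aged_114 (0.0543 to 0.0867), and 5 without KO_Aged_125 (0.0639 to 0.114). Among aged WT hearts, 3 ended without WT_Aged_12 (adjusted p = 0.05 to 0.0645), 9 without WT_Aged_4 (0.0508 to 0.0953), 9 without WT_Aged_5 (0.0505 to 0.127) and 6 without WT_Aged_1 (0.0738 to 0.164). With only these 8 libraries in the fit 17 genes were called, and 9 with the atrial score and 26 with the blood score as covariate.

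**Figure D3:**
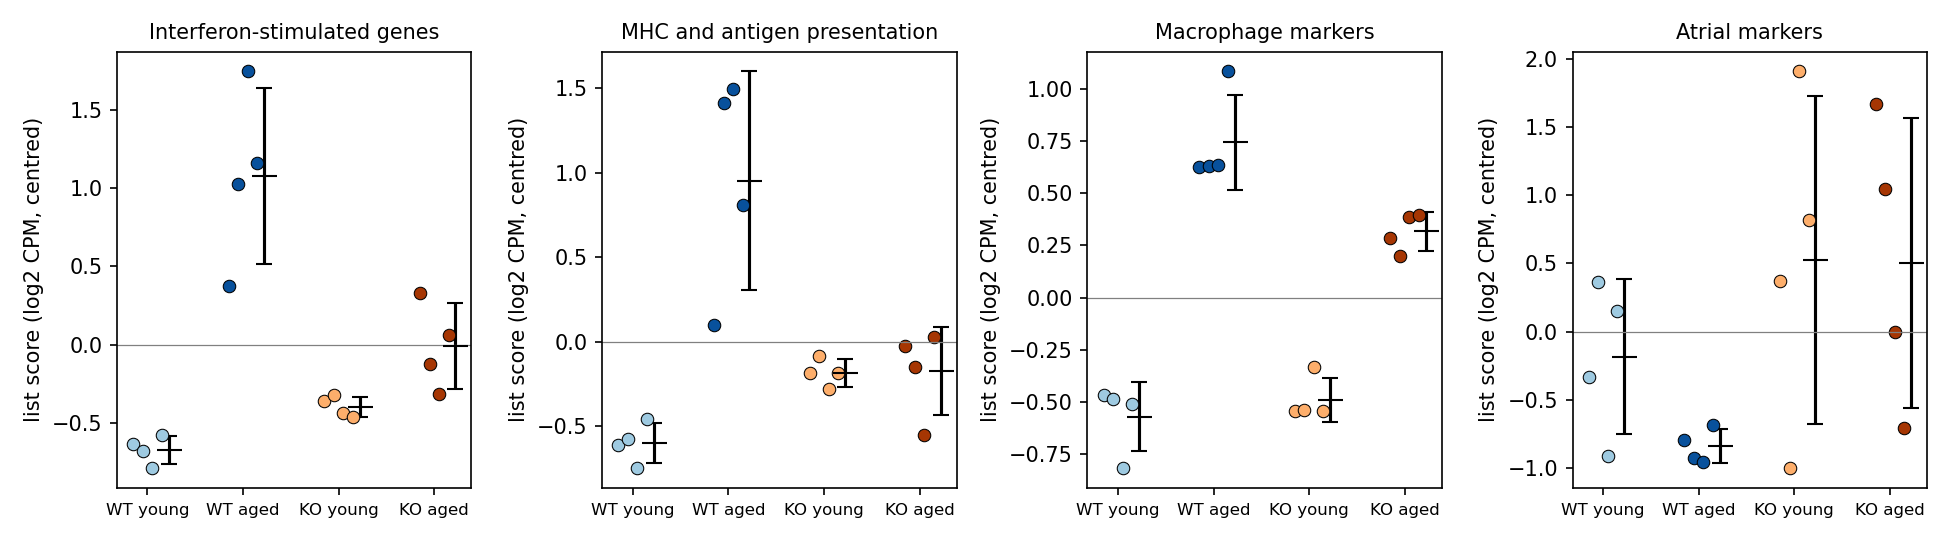
List scores (vertical axis, mean centred log2 CPM) in each of the 16 hearts (points) for 4 gene lists, with group mean and SD (bars, n = 4). WT_Aged_12 lies lowest of the aged WT hearts in the interferon score (0.37) and the antigen presentation score (0.10). Atrial scores of KO hearts reach 1.91.

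Ageing of KO hearts raised macrophage and complement genes, without a called change of antigen presentation genes. Of 18 macrophage markers 13 rose, also 13 adjusted over the list alone, with a median of 0.81 (camera adjusted p = 2.65e-18; adjusted p = 0.0424 with an estimated correlation). Cd209f rose by 2.71 ± 0.22 and Mrc1 by 0.81 ± 0.12 (SE; n = 4 per group, edgeR adjusted p = 3.32e-07 and 0.000259). Complement genes rose in 11 of 18 cases (15 adjusted over the list alone), with C3 up by 1.20 ± 0.19 from 165 ± 24.8 to 378 ± 51.6 CPM (SD) and the receptor gene C5ar1 by 0.89 ± 0.15 (adjusted p = 0.0902 with an estimated correlation). Of 35 interferon-stimulated genes 6 rose (7 adjusted over the list alone, median 0.30, adjusted p = 0.637 with an estimated correlation), among them Oas3 by 2.90 ± 0.55 and Oas2 by 0.55 ± 0.14. None of 20 antigen presentation genes passed by edgeR, over all genes or over the list alone (median 0.01, camera adjusted p = 0.845).

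Chemokine and acute inflammation genes rose in 8 of 28 cases and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.143 with an estimated correlation). Neutrophil markers rose in 2 of 5 cases (4 adjusted over the list alone), Csf3r by 1.13 ± 0.30 and S100a9 by 1.86 ± 0.50 (adjusted p = 0.235 with an estimated correlation). Senescence genes rose in 4 of 20 cases and fell in 1, also 4 and 1 adjusted over the list alone, with the glycoprotein gene Gpnmb up by 1.83 ± 0.26 (adjusted p = 0.143 with an estimated correlation). Cell cycle genes rose in 6 of 26 cases (12 rose and 1 fell adjusted over the list alone), with Mki67 up by 1.30 ± 0.22 (adjusted p = 0.295 with an estimated correlation). Antioxidant genes rose in 9 of 29 cases and fell in 1 (13 and 2 adjusted over the list alone), including the peroxidase Gpx3 by 0.75 ± 0.12 and G6pdx by 0.47 ± 0.11 (adjusted p = 0.0902 with an estimated correlation). Heat shock genes fell in 7 of 22 cases (10 adjusted over the list alone), with Hspb8 at -0.40 ± 0.08 and Dnajb1 at -0.60 ± 0.13 (adjusted p = 0.143 with an estimated correlation). The respiratory chain genes Ndufv1 and Uqcrc1 stood at -0.33 ± 0.08 and -0.29 ± 0.09, as the 2 of 76 in their list that fell (1 adjusted over the list alone; adjusted p = 0.717 with an estimated correlation). The sarcomere list was called lower at the preset correlation, with a median of -0.16 and 21 of 24 members negative. Over all genes 1 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone. The light chain Myl2 fell by 0.38 ± 0.11 on the log2 scale and Myot rose by 0.90 ± 0.10 (adjusted p = 0.432 with an estimated correlation). In the TGF-beta list 3 of 21 rose (5 rose and 1 fell adjusted over the list alone), including Tgfbi by 0.70 ± 0.09 and Smad6 by 0.79 ± 0.15 (adjusted p = 0.589 with an estimated correlation). In the endothelial list 3 of 15 fell and 1 rose (7 and 3 adjusted over the list alone), with the water channel Aqp1 at -1.21 ± 0.14 (adjusted p = 0.589 with an estimated correlation). The lysosome, immediate early and ribosomal protein lists, with medians of 0.11, -0.35 and -0.07, were called only at the preset correlation (adjusted p = 0.172, 0.432 and 0.872 with an estimated correlation). Of the 16 list calls 12 held whichever heart was left out. TGF-beta, lysosome, ribosomal protein and endothelial calls were lost in 2 cases without KO_Aged_114 (adjusted p = 0.0905 to 0.154), 3 without KO_Aged_122 (0.0889 to 0.221), 4 without KO_Young_31 (0.0551 to 0.108), 1 without KO_Young_38 (0.126) and 2 without KO_Young_53 (0.0801 to 0.431).

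Among curated genes whose groups did not overlap, the largest rises in KO ageing included those of the lectin genes Cd209d and Cd209b, the cytochrome P450 genes Cyp4f15 and Cyp2b10 (4.85 ± 0.81), Dpp6, the potassium channel Kcnk1 (5.33 ± 0.61) and Ccl8 (4.18 ± 0.45). Young KO hearts held no count of Cd209d or Cyp4f15, so the exact 95% intervals of their ratios have only lower limits, of 16.5 and 14.7. They held 1 count each of Dpp6 and Cd209b, for ratios of 84.6 (95% interval 14.8 to 3379) and 72.2 (12.6 to 2891). The largest falls were those of the glutamine transporter Slc38a1 (-1.98 ± 0.22), Ddc (-1.97 ± 0.45), Map3k7cl (-1.94 ± 0.34), Lrrn1 (-1.88 ± 0.38), the clock gene Arntl (-1.75 ± 0.37), Spon2 (-1.69 ± 0.31), the nuclear receptor Nr4a3 (-1.69 ± 0.28) and Hrk (-1.68 ± 0.45). Nnt, named by the rule because part of it is deleted in the C57BL/6J substrain, fell by 0.55 ± 0.15 on the log2 scale in KO ageing and stood at 596 to 872 CPM in the 4 groups. In all, 1020 genes changed, 672 up and 348 down (65.9% up), and 274 changed more than 2-fold. On the log2(FPKM + 1) scale 81.2% of 914 changed genes were up. At 2097 genes (15.7%) the groups did not overlap, against 2.86% by chance. The count was 675 without KO_Aged_115 and 644 without KO_Young_53. Of the 38 named calls, those of Nnt, Hrk, Oas2, Uqcrc1, Myl2, Csf3r and S100a9 were each lost when some single heart was left out. Lost were 5 of them without KO_Aged_115 (adjusted p = 0.0649 to 0.152) and 5 without KO_Young_53 (0.0667 to 0.143). A further 4 each were lost without KO_Aged_114 (adjusted p = 0.0516 to 0.1), KO_Aged_122 (0.0595 to 0.121) and KO_Aged_125 (0.0529 to 0.102) and KO_Young_27 (0.0711 to 0.0875) and KO_Young_38 (0.0514 to 0.0752), and 3 without KO_Young_31 (0.0596 to 0.113).

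The ageing changes of interferon-induced and antigen presentation genes differed between the genotypes. The interaction, the ageing change in KO minus that in WT, had a median of -1.35 over 35 interferon-stimulated genes, where 8 passed over all genes and 28 adjusted over the list alone (camera adjusted p = 1.03e-46; adjusted p = 0.0315 with an estimated correlation). Over 20 antigen presentation genes it had a median of -1.54, with 7 passing over all genes and 20 adjusted over the list alone (adjusted p = 0.0315 with an estimated correlation). The difference was -1.85 ± 0.23 (SE) for Gbp5, -1.88 ± 0.24 for Gbp7, -1.70 ± 0.22 for Gbp2 (edgeR adjusted p = 0.00198 each) and -2.13 ± 0.29 for Gbp3. Macrophage markers had a median of -0.58, with none of 18 passing over all genes and 9 adjusted over the list alone (adjusted p = 0.211 with an estimated correlation). The interaction also holds the KO change in young hearts. There the interferon and antigen presentation lists had medians of 0.27 and 0.40, against -0.98 and -1.18 in aged hearts.

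Among curated genes that passed, the largest negative differences were those of Tgtp2 (-3.44 ± 0.60), Tgtp1 (-2.98 ± 0.59), the Fc receptor Fcgr4 (-2.82 ± 0.55), Gbp4 (-2.66 ± 0.42) and H2-Q7 (-2.59 ± 0.49). B2m and H2-Q6 stood at -1.60 ± 0.30 and -2.22 ± 0.40. Tgtp1 with Tgtp2, and H2-Q6 with H2-Q7, are similar gene pairs whose reads can be split between the copies, so their separate values are uncertain. The largest positive differences were those of the Wnt antagonist Sfrp5 (3.27 ± 0.59), Necab1 (2.64 ± 0.45), Zbed6 (1.64 ± 0.30), Sstr3 (1.61 ± 0.24) and the glycerol phosphate dehydrogenase Gpd1 (1.08 ± 0.16). Zbed6 lies inside an intron of Zc3h11a, so reads of the host transcript can count for it. Col6a2 had a difference of 0.76 ± 0.16, in a matrix list with a median of 0.42, 1 of 35 passing over all genes and 9 adjusted over the list alone (adjusted p = 0.286 with an estimated correlation). Gstm2 had -0.62 ± 0.12 (antioxidant list, adjusted p = 0.286 with an estimated correlation). Erythroid markers had a median of -0.92 with none of 9 passing over all genes and 6 adjusted over the list alone (adjusted p = 0.211 with an estimated correlation).

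In all, 62 genes had a different ageing change, 17 positive and 45 negative, and 19 of 35 lists were called, 2 of them with an estimated correlation. Of these list calls 13 held whichever heart was left out, those of interferon and antigen presentation genes among them. The ion channel, lysosome, heat shock, antioxidant, fibroblast and smooth muscle calls did not. They were lost in 3 cases each without KO_Aged_115 (adjusted p = 0.0712 to 0.0966) and KO_Young_53 (0.0778 to 0.101), 4 without WT_Young_29 (0.0688 to 0.151), and 2 each without KO_Young_38 (0.0656 to 0.0897) and WT_Aged_12 (0.0722 to 0.0733). A single one was lost without KO_Aged_122 (adjusted p = 0.0711), KO_Young_31 (0.17), WT_Aged_4 (0.0888), WT_Aged_5 (0.315), WT_Aged_1 (0.0743), WT_Young_34 (0.0531) or WT_Young_42 (0.0833). The gene count was 26 without KO_Aged_115, 29 without KO_Aged_122, 28 without KO_Young_27, 25 without KO_Young_31, 39 without KO_Young_53, 40 without WT_Aged_4, 171 without WT_Aged_12, 30 without WT_Young_29, 31 without WT_Young_34, 35 without WT_Young_39 and 30 without WT_Young_42. It was 7 with the blood score and 29 with the atrial score as covariate. For 18 named genes the interaction call was followed with single hearts left out. The calls of Tgtp1, Tgtp2, Fcgr4, H2-Q7, H2-Q6, B2m, Col6a2 and Gstm2 were lost when some single heart was left out. All 8 were lost without KO_Aged_115 (adjusted p = 0.0578 to 0.103), 7 without KO_Young_31 (0.0544 to 0.118), KO_Young_53 (0.0562 to 0.0955) or WT_Young_29 (0.0601 to 0.086). Lost were also 6 without KO_Young_27 (adjusted p = 0.0508 to 0.065), WT_Young_34 (0.0715 to 0.0957) or WT_Young_39 (0.062 to 0.121), and 5 without KO_Aged_114 (0.0518 to 0.0756) or KO_Aged_122 (0.0552 to 0.0979) or WT_Aged_4 (0.054 to 0.079). Fewer were lost elsewhere, 3 without WT_Aged_5 (0.0524 to 0.0729) or WT_Aged_1 (0.0566 to 0.0691) or WT_Young_42 (0.0527 to 0.0782), and 2 without KO_Young_38 (0.0646 each).

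In young hearts the main fit called 36 genes in KO against WT, and in aged hearts 117. This order depended on the fit, and it reversed with only the 8 libraries compared and with limma voom. An unadjusted edgeR p under 0.05 was found for 1467 genes in young and 1454 in aged hearts. Rrad, a small GTPase that restrains calcium channels, rose by 0.89 ± 0.11 (SE) from 94.9 ± 15.4 to 176 ± 22.6 CPM (SD, n = 4; edgeR adjusted p = 0.000923). Gpd1 fell by 0.87 ± 0.11 on the log2 scale, from 116 ± 16.8 to 63.6 ± 8.65 CPM (adjusted p = 0.00123). The other rises were those of Sox4 (0.79 ± 0.16), the cadherin Cdh4 (0.74 ± 0.15), Ccn1 (0.67 ± 0.13), the autophagy receptor Sqstm1 (0.55 ± 0.09), Htatip2 (0.48 ± 0.10) and transketolase Tkt (0.48 ± 0.10). After Armh4, the largest falls among curated genes without overlap were those of angiotensinogen Agt (-1.88 ± 0.33), the tachykinin precursor Tac1 (-1.20 ± 0.23), Zbed6 (-1.15 ± 0.22), Sstr3 (-0.91 ± 0.17), Gpd1, Tmem100 (-0.83 ± 0.17) and Noct (-0.80 ± 0.16). Interferon-stimulated genes had a median of 0.27 with none of 35 passing by edgeR, over all genes or the list alone (Rsad2 at 0.48 ± 0.14 and Gbp5 at 0.54 ± 0.17). Antigen presentation genes had a median of 0.40 with none of 20 passing either way (H2-Q7 at 0.94 ± 0.36). The changes were positive in 29 of 35 and in 20 of 20 members. Camera calls of these lists were lost with an estimated correlation (adjusted p = 0.739 and 0.681). Interferon scores were -0.46 to -0.32 in young KO and -0.79 to -0.58 in young WT hearts. Antigen presentation scores were -0.28 to -0.08 and -0.75 to -0.46. Neither score overlapped between the groups, which chance gives in 2.86% of cases.

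Of the unfolded protein response genes 1 of 29 fell (3 adjusted over the list alone), the chaperone Hspa5 at -0.39 ± 0.08, while Manf, also at -0.39 ± 0.11, did not pass (adjusted p = 0.143). Respiratory chain genes had a median of 0.13 with none of 76 passing either way, with Sdhb at 0.22 ± 0.08 and Ndufa1 at 0.29 ± 0.11. The TGF-beta and matrix lists had medians of -0.08 and -0.17, with the matrix gene Timp4 at -0.49 ± 0.17 (adjusted p = 0.294). Atrial and erythroid markers had medians of 0.50 and 0.51, with Myl7 at 2.69 ± 1.33, Fgf12 at 1.98 ± 0.88, Hba-a1 at 0.52 ± 0.26 and Hba-a2 at 0.51 ± 0.23, none of which passed. The alpha globin genes are near-identical and their separate values uncertain. The antioxidant list had a median of 0.10, with Gstm2 at 0.31 ± 0.08 (adjusted p = 0.134). Fatty acid oxidation, heat shock, hypertrophy, ribosomal protein and smooth muscle lists were also called at the preset correlation, with medians of -0.07, -0.11, -0.07, 0.07 and -0.26. All 14 list calls in young hearts were lost with an estimated correlation, the lowest adjusted p then being 0.681. At the preset correlation 8 of the 14 were lost with some heart left out. Lost were 1 without KO_Young_27 (adjusted p = 0.0746), 3 without KO_Young_31 (0.16 to 0.225), 3 without KO_Young_38 (0.0618 to 0.574), and 5 without KO_Young_53 (0.0612 to 0.503). Among young WT hearts, 5 were lost without WT_Young_29 (0.0974 to 0.221), 3 without WT_Young_34 (0.0842 to 0.106) and 4 without WT_Young_39 (0.0512 to 0.42). The number of lists called was 9 without KO_Young_53.

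In all, 36 genes changed in young KO hearts, 7 up and 29 down, 4 of them more than 2-fold. At 1135 genes (8.49%) the groups did not overlap, against 2.86% by chance. Every heart mattered to this count, which was 7, 4, 7 and 21 without KO_Young_27, KO_Young_31, KO_Young_38 and KO_Young_53, and 8, 19, 4 and 7 without WT_Young_29, WT_Young_34, WT_Young_39 and WT_Young_42. Of the 16 named calls only those of Armh4, Rrad and Gpd1 held whichever heart was left out. The others were lost in 12 cases without KO_Young_27 (adjusted p = 0.089 to 0.167), 13 without KO_Young_31 (0.0534 to 0.203), 12 without KO_Young_38 (0.0514 to 0.0747), and 7 without KO_Young_53 (0.0712 to 0.132). Among young WT hearts, 10 were lost without WT_Young_29 (0.0674 to 0.145), 9 without WT_Young_34 (0.0522 to 0.125), 13 without WT_Young_39 (0.058 to 0.173) and 11 without WT_Young_42 (0.0821 to 0.12). With only the 8 young libraries in the fit 135 genes were called, 149 by DESeq2 and 187 by limma voom.

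Hearts of both genotypes shared much of the ageing change. The log2 ageing changes in WT and KO hearts, which share no library, correlated across 13373 genes with Pearson r = 0.671 and Spearman rho = 0.571, and 70.4% of genes had the same sign. Genes are not independent replicates. Among called genes 472 were higher with age in both genotypes, against 79.3 for independent lists, and 206 were lower in both, against 34.6. The SD of the changes over genes was 0.516 in WT and 0.365 in KO hearts. The KO changes in young and aged hearts correlated with r = -0.0949 and rho = -0.0671. Armh4 was the 1 gene lower in KO at both ages, and Sstr3 passed in opposite directions, at 0.69 in aged and -0.91 in young hearts. Armh4 and Sstr3 were the only genes called at both ages.

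**Figure D4:**
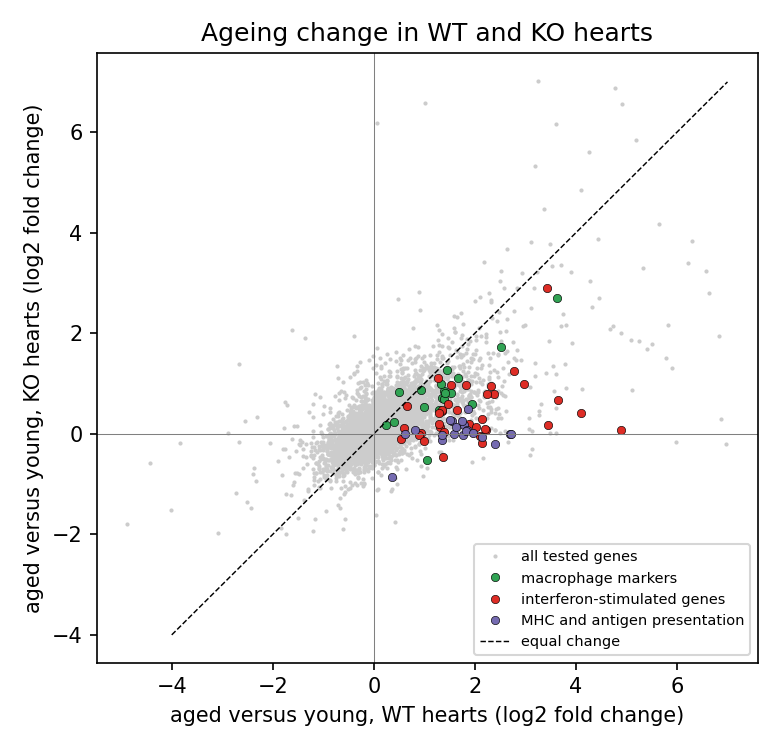
Log2 fold change with age in WT hearts (horizontal axis) and in KO hearts (vertical axis) for 13373 tested genes (grey), with macrophage markers, interferon-stimulated genes and antigen presentation genes coloured and a dashed line of equal change. Antigen presentation genes have a median of 1.76 in WT and 0.01 in KO hearts, and macrophage markers 1.36 and 0.81.

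Most genes called lower in aged KO hearts were among those raised by ageing in WT hearts. Of the 95 genes lower in aged KO against aged WT hearts, 88 were among the 1578 raised with age in WT. Of the 22 higher ones, 18 were among the 1328 lowered with age. In the other directions 0 and 1 genes were shared. Both comparisons use the aged WT hearts with opposite signs, which alone gives a negative relation, and the overlap that this alone would give was not computed. The observed r was -0.641, against -0.494 (-0.525 to -0.472) for simulated unchanged groups, and the covariance was -0.0934, against -0.0170, a difference of -0.0764. Spearman rho was -0.492, against -0.464 (-0.477 to -0.446), and 32.9% of genes had the same sign, inside the simulated range of 32.7% to 34.7%. The simulated groups held no ageing change, unlike the hearts. The simulated r, rho and share of the same sign are therefore not like for like, and no conclusion is drawn from them. With aged WT hearts divided so that no library was shared, r was -0.407 on average over the 6 divisions (-0.475 to -0.298), rho -0.198 and the covariance -0.0694 (-0.0812 to -0.0559), and 45.0% of genes had the same sign.

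The spread between hearts was higher in aged WT hearts than in the other groups, without passing a test. The distance of a heart from its group mean was 30.7 ± 5.64 in aged WT, 24.6 ± 2.62 in young WT, 25.1 ± 1.42 in aged KO and 25.9 ± 1.07 in young KO hearts (SD, n = 4, log2 CPM over 13373 genes). Exact two-sided permutation tests gave p = 0.114 for aged against young WT and for aged KO against aged WT (adjusted p = 0.229 over 4 comparisons). The same exact tests gave p = 0.486 for aged against young KO and p = 0.4 for young KO against young WT. With 4 hearts per group the smallest possible p is 0.0286, so a difference in a single comparison could not pass 0.05 after adjustment over 4.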

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

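The tests of macrophages, cohorts, atrial tissue, transcript length, GC content and time of day were chosen only after the results they bear on had been seen.

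In 323 groups of 4 hearts, formed by the named genes and list scores, the highest or lowest heart was tested for its gap to the nearest heart as a share of the group's range. The share exceeded Dixon's 95% critical value in 27 groups, where chance gives about 1 in 20 groups, or 16.15. Of these, 8 were in aged WT, 7 in young WT, 5 in aged KO and 7 in young KO hearts, most often WT_Aged_1 (4 times), then KO_Young_38, KO_Aged_125 and WT_Young_42 (3 times each).

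In aged WT hearts, WT_Aged_1 stood highest in the macrophage score (0.976) and Plac8 (0.918) and lowest in Klf4 (0.956) and Csf3r (0.936). WT_Aged_4 stood lowest in Alas2 (0.971) and highest in Fkbp10 (0.982), and WT_Aged_12 lowest in Col6a3 (0.923) and highest in Kcnj3 (0.894). In young WT hearts, WT_Young_39 stood lowest in C1qa (0.942) and the macrophage score (0.881), WT_Young_42 highest in Fgf12 (0.895) and Tgtp2 (0.948), and WT_Young_29 lowest in Zbed6 (0.970). Chil3 in WT_Young_34 and Ubd in WT_Young_42 (a share of 1 each) rest on 1 or 2 counts over the group.

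In aged KO hearts, KO_Aged_125 stood highest in Il1b (0.837) and the erythroid score (0.870) and lowest in Col6a2 (0.856). KO_Aged_122 stood lowest in B2m (0.905) and KO_Aged_115 lowest in Gstm2 (0.859). In young KO hearts, KO_Young_38 stood highest in the macrophage score (0.983) and Oas3 (0.993) and lowest in Armh4 (0.871). KO_Young_53 stood lowest in Cyp2b10 (0.980) and KO_Young_31 lowest in Sfrp5 (0.832), while Cd209b in KO_Young_31 and Dpp6 in KO_Young_53 (a share of 1 each) rest on a single count.

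The interaction test called 25 of the named genes, and camera with an estimated correlation 2 of the lists, with different ageing changes in the genotypes. The difference, KO minus WT, was negative on the log2 scale for Gbp2 (-1.70), Gbp3 (-2.13), Gbp4 (-2.66), Gbp5 (-1.85), Gbp7 (-1.88), Rsad2 (-1.14), Tgtp1 (-2.98) and Tgtp2 (-3.44), all induced by interferon. It was also negative for B2m (-1.60), H2-D1 (-1.28), H2-DMb1 (-1.48), H2-Q6 (-2.22), H2-Q7 (-2.59), H2-T23 (-1.22), Fcgr4 (-2.82), Gstm2 (-0.62) and Htatip2 (-0.63). It was positive for Col6a2 (0.76), Fkbp10 (0.96), Podn (0.90), Gpd1 (1.08), Sstr3 (1.61), Zbed6 (1.64), Necab1 (2.64) and Sfrp5 (3.27). The interaction calls of Rsad2, H2-D1, H2-DMb1, H2-T23, Htatip2, Fkbp10 and Podn were not followed with single hearts left out. The list medians were -1.35 for interferon-stimulated and -1.54 for antigen presentation genes.

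The lower interferon and antigen presentation genes of aged KO hearts were weighed first. A single aged WT heart as the whole cause is argued against, since the interferon median stayed at -0.69 or below whichever was left out (nearest to 0 without WT_Aged_5). Fewer macrophages may be part of the cause: the combined score differed by -1.11 and the macrophage score by -0.43 (exact two-sided permutation p = 0.0286 each, the smallest possible), but their difference gave p = 0.171. A cohort difference cannot be told apart from genotype, since 0 aged WT animals were numbered inside the range of the aged KO animals. An effect of Armh4 loss stays open beside these.

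Atrial markers were uneven between hearts. Different amounts of atrial tissue may be the cause: the log2 ratio of Sln to Myl7 had an SD of 34% of that of Myl7, between the bounds of 30% and 60% set for a shared and an independent source. A rise in every KO heart was not seen, but 6 of 8 KO hearts scored above each WT heart of their age, so genotype and dissection cannot be told apart here.

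WT_Aged_1 lay apart from the other aged WT hearts. Its deviation correlated with transcript length at -0.23, against up to 0.327 in size in another heart and a median of 0.172 in the others. That met the bound set against a length bias. A larger correlation in another heart cannot exclude a length bias in WT_Aged_1, so transcript length stays open. For GC content the correlation was -0.45, against 0.470 in size in another heart when WT_Aged_1 was part of the other hearts' reference, and 0.423 when it was left out of it. That second reference was added after the result of the first had been seen, and the references disagree, so GC bias stays open. Its clock score deviated from its group by -0.78 on the log2 scale, against at most 0.61 in the others, so another time of day at collection may contribute. The score also differed between groups, at 3.01 to 3.89 in young KO and 4.01 to 4.55 in young WT hearts. It was 4.39 to 4.77 in aged KO and 3.16 to 4.15 in aged WT hearts. Time of day thus cannot be told apart from genotype at either age, nor from age in KO hearts. The score includes Arntl, which fell in KO ageing. No biological explanation was tested for this heart.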

How the results depend on the processing

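The fits with an atrial or a blood score as covariate were chosen only after the data had been seen. No paired analysis was possible because no animal number occurs in more than 1 group. A fit with Y-gene levels as covariate was not run, since hearts differed by only 0.41 log2.

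Of 141 called gene results, 59 kept their call under each alternative run, 82 lost it under some and 0 reversed. Of 87 called list results, 13 kept it, 74 lost it under some and for 3 the direction of the camera test reversed, all with the blood score. These were ribosomal proteins in young KO against WT (median -0.0177) and in WT ageing (-0.125), and respiratory chain genes in the interaction, whose median kept its sign (-0.00824) and was not called (adjusted p = 0.962).

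The 117 genes changed in aged KO hearts became 263 with DESeq2, 51 with limma voom, 67 on the log2(FPKM + 0.1) scale, 17 with only the 8 libraries compared, 9 with the atrial and 26 with the blood score. The 36 in young hearts became 149 with DESeq2, 187 with limma voom, 17 on the log2(FPKM + 1) scale, 8 on that scale without a filter, 135 with only the 8 libraries and 7 with the atrial score. WT ageing went from 2906 to 297 genes with the blood score. The interaction went from 62 to 213 with DESeq2, 39 on the unfiltered log2(FPKM + 1) scale, 29 with the atrial and 7 with the blood score. With an estimated correlation the lists called were 3 of 20 and 0 of 14 for KO against WT in aged and young hearts, 7 of 18 and 1 of 16 for ageing in WT and KO, and 2 of 19 for the interaction. With the blood score they were 12, 8 and 11 for aged KO, young KO and the interaction. The cause was not tested. Spearman coefficients were -0.492 and 0.571 in place of -0.641 and 0.671. With only 9699 genes at log2 CPM of 3 or more, mean distances between hearts were 21.6 in aged KO, 22.2 in young KO, 32.5 in aged WT and 20.8 in young WT hearts, against 41.0, 42.2, 50.1 and 40.2. Fewer genes enter the sum, which lowers the distances of every group. Aged WT hearts lay farthest apart in both sets of genes. The exact tests of spread were run on all tested genes only.

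With single hearts left out, genes changed ranged from 31 (without KO_Aged_115) to 251 (without WT_Aged_12) in aged KO hearts, 4 to 21 in young KO hearts, 2111 to 2926 in WT ageing, 644 to 875 in KO ageing and 25 to 171 in the interaction. Lists called ranged over 15 to 18, 9 to 14, 17 to 20, 12 to 19 and 15 to 23. The correlations ranged from -0.685 to -0.598 for WT ageing with the aged KO change, 0.627 to 0.701 for both ageing changes and -0.137 to -0.0306 for both KO changes.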

Other observations

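Of the tests in this part, the values of Nnt and of the untested lists follow rules fixed before the data were examined, and only the covariance drawn from the spread of aged WT hearts was chosen after the result had been seen.

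Nnt, which encodes a mitochondrial transhydrogenase, stood at 664 ± 95 CPM in young WT, 649 ± 61.4 in aged WT, 872 ± 219 in young KO and 596 ± 60 in aged KO hearts (SD, n = 4). It was thus expressed in each group. Xist was not analysed here. The lists with too few members for a test had medians of -0.44 (B and plasma cells, 1 member), -0.32 (lung and thymus, 1 member), 0.30 (skeletal muscle, 4 members) and -0.03 (Y chromosome, 4 members) in aged KO against WT. They were 1.38, 0.52, -0.04 and -0.04 in WT ageing. Mitochondrially encoded genes were not in the table tested.

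For several uncalled lists the median, mean and test differed in sign. They were the respiratory chain, p53, heat shock and cholesterol lists in aged KO against WT; the senescence, adipocyte and mesothelial lists in young KO against WT; and the glycolysis, hypertrophy, fibroblast and endothelial lists in WT ageing. In KO ageing they were the hypertrophy, calcium, matrix, clock, cholesterol and atrial lists, and in the interaction the sarcomere, hypertrophy and STAT3 lists.

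Loss of Armh4 may oppose the ageing change of WT hearts across genes, as a hypothesis. With no shared library the covariance of the aged KO change and the WT ageing change was -0.0694 on average, and below 0 in all 6 divisions of the aged WT hearts. Genes with large changes weigh most in a covariance. In the same divisions Spearman rho was -0.198 on average (-0.274 to -0.104). The share of genes with the same sign was 45.0% (41.7% to 48.3%), so many genes did not follow the relation. The covariance with shared libraries, -0.0934, lay below that of each simulation of unchanged groups, while the share of genes with the same sign, 32.9%, lay inside their range of 32.7% to 34.7%. The simulations held no ageing change, so the share of the same sign with shared libraries cannot decide here. The covariance drawn from the spread of the aged WT hearts alone was -0.0240, larger in size than the simulated mean of -0.0170. A cohort difference of the aged animals would give the same sign, and stays open.

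Other splits of the same hearts tested the counts of genes. No other split gave as many as the 117 genes in aged KO hearts (34 in the highest other of 35 splits, 1 as large with the real one) or the 36 in young KO hearts (0 in the highest other, 1 of 35). The same held for the 2906 in WT ageing (0, 1 of 35), the 1020 in KO ageing (0, 1 of 35) and the 62 in the interaction (2, 1 of 60). With 35 splits, 1 of 35 is the smallest share possible. Chance is thus argued against for each count by itself. No adjustment over the counts was made, so chance is not excluded. For lists called at the preset correlation chance could not be excluded in aged KO against WT (20, with 20 in the highest other; 3 of 35 splits as large), young KO against WT (14 and 17; 11 of 35), WT ageing (18 and 21; 10 of 35) or KO ageing (16 and 22; 10 of 35). In the interaction 1 other split called as many lists as the real one (19 and 19, 2 of 60). That share met the bound for excluding chance fixed before the data were examined. With another split equal to the real one, chance is still left open. Splits other than the real one called a median of 12.5, 10, 14, 13 and 12 lists, so a preset call by itself carries little weight. For lists called with an estimated correlation chance could not be excluded in aged KO against WT (3, with 3 in the highest other, 3 of 35 splits as large) or KO ageing (1 and 2, 6 of 35). In young KO against WT the real count was 0, with 2 in the highest other. All 35 splits then had as many by definition, so the splits could not decide there. In WT ageing no other split called as many (7 and 0; 1 of 35). In the interaction 1 other split called more lists than the real one (2 and 5; 2 of 60), so chance is left open there.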
